A study of Schizosaccharomyces pombe with 5 samples.

How the data were processed

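RNA of fission yeast (Schizosaccharomyces pombe, the heterothallic h minus strain L972) was compared on 5 cDNA arrays with 2 dyes each. Per the labels, cells were starved of nitrogen for 48 h in minimal medium without a nitrogen source, which brings them to a resting state called G0. They then received 4 volumes of fresh complete minimal medium at 26 °C. Nitrogen and fresh medium thus came together, and no array had fresh medium without nitrogen, so their effects cannot be told apart. Polyadenylated RNA (3 to 6 µg) was labelled. Per the labels, the Cy5 dye marked RNA of cells 1, 2, 3.5 or 6 h after nitrogen came back, or of cells in vegetative (logarithmic) growth, and the Cy3 dye marked RNA of G0 cells on each array. There was 1 array per condition, and the submitters' design text says that no experiment was repeated. It also reports Northern hybridization of 56 genes, 35 of them with consistent results; those values were not used here. The free-text descriptions of the 3.5 h, 6 h and vegetative samples name 2 h, against their titles, sources and treatment protocols, which were followed here.

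The deposited values are log ratios per spot, taken here as log2 ratios of growing cells over G0 cells. The base of the logarithm is not given in the sources used here and base 2 is an assumption. Direction was taken from the dyes in the labels. Image analysis, background correction and normalization are not given in the sources used here. Spot intensities were not used here, so no filter on dim spots could be set and the precision rests on the number of arrays. Gene medians were 0.06 at 1 h, 0.00 at 2 h, 0.14 at 3.5 h, 0.04 at 6 h and 0.09 in vegetative cells, so the columns were near 0 but not centred on it. The columns came in 2 sets: values of the 1 h and 2 h arrays had 9 decimals and those of the 3.5 h, 6 h and vegetative arrays had 3. The labels do not say whether 1 preparation of G0 RNA served all arrays, so a difference across the sets can hold a difference between G0 preparations.

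The table held 5188 rows, of which 5184 were spots in 16 blocks of 324 and 4 were rows of the authors' averages, left out here. Platform annotation named 1 gene for 4865 spots, several genes for 22 and none for 297. Of the 4865, 4839 had an Entrez identifier in the RefSeq gene table of assembly ASM294v3, which was used for names, synonyms and chromosomal neighbours. No coordinates are given because the arrays name no genome build. Spots of 1 gene were averaged, which gave 4797 genes with a value on at least 1 array and 4708 with a value on all 5. The genes cdc2, nda3 and nuc1 were spotted in all 16 blocks and measured the error within an array. The authors' average for nda3 at 1 and 2 h leaves out 1 spot, and that spot was left out on all arrays here. Pooled over these 3 genes the SD between spots was 0.25, 0.22, 0.22, 0.24 and 0.18 in array order. Pooled over 12 unnamed positions repeated in each block it was 0.44, 0.43, 0.40, 0.47 and 0.38. Most genes had 1 spot, so no error can be given for their values.

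Before the data were examined, a gene was set to count as different when its log2 ratio, or its difference between 2 arrays, was at least 1 or at most -1, which is a rule of size and not a test. The median of each of 30 gene lists was ranked among 10000 random lists of the same size, and a list stood apart below the 0.5th or above the 99.5th percentile. About 1.5 of the 150 list medians against G0 would do so by chance, and as many of the 150 between arrays. Random lists could not be matched on expression level. A listed symbol was taken as the gene that bears it now, and 40 of 1286 list memberships carry a symbol that is also an older name of another gene. The proteasome list holds the subunit gene rpn10 and also pus1, an older name of rpn10 that now names a different gene, which is the one spotted. That gene, singled out after its values were seen, was the highest of the list on every array (2.73 at 1 h). A trend over the 4 time course arrays was fitted with limma 3.58.1 in R 4.3.3 (log2 ratio on log2 hours, empirical Bayes, Benjamini-Hochberg adjusted p under 0.05), with 2 residual degrees of freedom. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

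Named genes were fixed by rule: per array the 10 highest and 10 lowest among genes moving at least 1.5-fold the same way on an adjacent array, per pair of arrays the 10 largest and smallest differences, for the trend the 10 steepest slopes either way, up to 4 members of each list with the largest values, and a set of cell cycle, starvation and growth markers. Of these markers, ste9 had no value under that symbol, and 1 other item is not reported here. Not every gene of these sets is named, and any other gene is said to be chosen after its values were seen.

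The trend step was tested on simulated data over 4730 genes. It recovered 198 of 200 genes changed 2-fold per doubling of time, with 17 false calls, and 200 of 200 changed 4-fold, with 7 false calls. All simulated genes shared 1 normal scatter, set by the median residual variance of the real fit, and the changed ones followed a straight line. Recovery among real genes, whose scatter and time courses differ, was not measured and may be lower. Simulated lists of 30 genes at 1 h stood apart in 1 of 60 cases with no shift, 12 of 60 with a shift of 0.5 and 52 of 60 with a shift of 1. Alternatives were centring, scaling arrays to 1 median absolute deviation, a 3-fold limit, genes with all values, other ways to combine spots, list means and other trend fits. Reading the values as natural logarithms, centring each block, adding the set of columns to the trend fit and leaving pus1 out of the proteasome list were chosen after seeing the data, as were the further gene lists used in the closing section.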

Results

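Growing cells of fission yeast in 5 conditions were each set against nitrogen-starved G0 cells on 1 array, to follow gene expression as resting cells return to growth and division. The 5 arrays held 1, 2, 3.5 and 6 h after nitrogen replenishment and vegetative growth. Each gave between 4765 and 4781 genes a log2 ratio of growing over G0 cells. No difference below has a replicate check, and the only error measured in these values is that between repeated spots of an array (pooled SD 0.18 to 0.25 for cdc2, nda3 and nuc1, and 0.38 to 0.47 for 12 unnamed repeated positions). At the larger SD, error alone would put 20.9 to 80.4 genes per array past 2-fold in each direction. The cyclin-dependent kinase gene cdc2 had log2 ratios of 1.84 ± 0.31 (SD, 16 spots) at 1 h and 0.26 ± 0.20 (SD, 16 spots) in vegetative cells. The RNA polymerase I gene nuc1 stood at 3.45 ± 0.26 (SD, 16 spots) at 1 h and at 0.79 ± 0.20 (SD, 16 spots) in vegetative cells. The beta-tubulin gene nda3 was at -0.12 ± 0.16 (SD, 15 spots) at 1 h and at 1.10 ± 0.13 (SD, 15 spots) in vegetative cells. Across the 4708 genes measured on all arrays, 3141 (66.7%) were at least 2-fold different from G0 on at least 1 array, 365 were 2-fold higher on all 5 and 287 were 2-fold lower on all 5.

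At 1 h after nitrogen came back, genes for making ribosomes lay far above G0. Of 134 ribosome biogenesis factors, 124 were at least 2-fold higher, with a median log2 ratio of 2.66, led by erb1 (4.07), rrb1 (3.92) and utp4 (3.72). Of 122 cytosolic ribosomal protein genes, 119 were 2-fold higher (median 2.22), and rpl501 lay below G0 at -2.79. Purine and pyrimidine synthesis genes had a median of 2.31, with 18 of 19 at least 2-fold higher and ura3, the dihydroorotate dehydrogenase gene, at 4.58. RNA polymerase I and III genes had a median of 1.58 with 20 of 32 higher, translation factors 1.68 with 32 of 39 higher, and cytosolic aminoacyl-tRNA synthetases 1.16 with 13 of 22 higher. The amino acid synthesis list had a median of 1.07 with 40 of 77 genes higher and 6 lower. Among its highest were met17 of sulfur amino acid synthesis (5.69) and the S-adenosylmethionine synthetase gene sam1 (5.07). A symbol pattern filled part of that list and took in trp663 and trp1322, so not every member need be a synthesis gene. All 7 of these lists stood apart above random lists of their size.

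Genes of carbon metabolism, autophagy, peptidases and the stress response lay below G0 at 1 h. Glycolysis and fermentation genes had a median of -2.08 with 15 of 20 at least 2-fold lower, among them the phosphoglycerate kinase gene pgk1 (-5.38) and fbp1, the gluconeogenic fructose bisphosphatase gene (-5.16). Of 18 tricarboxylic acid cycle genes 10 were 2-fold lower and 2 higher (median -1.75), with mdh1 at -4.77 and cit1 at -4.18. Hexose transporter genes had a median of -1.49 at the 0.48th percentile, with ght5 at -6.73 and ght3 at -6.11, while ght2 was more than 2-fold above G0. Autophagy genes had a median of -1.47 with 23 of 33 lower, including atg8 (-2.68). The list of vacuolar and secreted peptidases had a median of -2.18 with 10 of 14 lower. Among these was ams1 (-4.90), which encodes a mannosidase and not a peptidase. Stress response genes had a median of -1.31 with 20 of 34 lower and 7 higher, and actin and tubulin cytoskeleton genes -1.04 with 13 of 25 lower, such as arc1 (-3.22), whereas act1 itself was at 0.34. These 7 lists stood apart below random lists, the hexose transporters only at the limit. Among redrawn random lists the same hexose transporter median lay at the 0.65th percentile with only genes with all values. It lay at the 0.66th with medians of repeated spots, so the call was lost in both. Scaled arrays (-1.20) put the list at the 0.54th. Scaling multiplies an array by 1 factor and cannot change a rank against G0, so that move came from redrawn random lists. The nitrogen starvation list (median -0.62, 14 of 33 genes lower and 8 higher) and the sexual differentiation list (-0.60, 11 of 32 lower) did not stand apart at 1 h, although the mean of the latter (-0.78) did. The respiratory chain (-0.56) did so only by its mean (-0.64). The proteasome (-0.69, at the 0.54th percentile) stood apart in 5 alternatives, among them scaled arrays (-0.56) and the list without pus1 (-0.70). With scaled arrays only the random lists had changed, since its rank could not. With genes with all values, or medians or the first of repeated spots, its rank among redrawn random lists moved but its median did not. In all, 1118 genes were at least 2-fold higher and 1078 lower out of 4769, led by psu2 (7.16), the carbonic anhydrase gene nce103 (6.68) and the amino acid transporter gene aat1 (5.86) above G0 and mug14 (-6.88) below it.

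At 2 h the same 7 growth lists stood above G0 and 10 lists below it. Ribosome biogenesis factors had a median of 2.46 with 123 of 135 at least 2-fold higher, and ribosomal proteins 2.28 with 119 of 122 higher. The stress response list had its lowest median here, -2.51, with 25 of 33 genes 2-fold lower and 3 higher, the low ones including lsd90 (-6.55), the metallothionein gene zym1 (-6.07), the catalase gene ctt1 (-5.41) and hsp9 (-4.90). Nitrogen starvation and salvage genes had a median of -1.05 with 17 of 33 lower and 8 higher. The amino acid permease genes isp5 (-5.45) and put4 (-2.60) and the protease gene isp6 (-4.43) were on the low side and aat1 (6.48) and cat1 (3.36) on the high side. The mean of that list, -0.72, did not stand apart. Sexual differentiation genes had a median of -1.10 with 17 of 32 lower, including the mating pheromone gene mfm1 (-6.25) and the meiosis regulator mei2 (-1.90). Glycolysis (median -2.46), autophagy (-1.66), peptidases (-2.33), the tricarboxylic acid cycle (-1.21) and hexose transporters (-1.80) remained lists below G0. The proteasome (-0.64) and the respiratory chain (-0.54) also stood apart, and the means of both lists did not. Among genes with all values the respiratory chain (-0.53, at the 0.505th percentile) did not either. Out of 4781 genes, 1088 were 2-fold higher and 1020 lower.

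At 3.5 h and 6 h chaperone genes joined the lists above G0, and glycolysis (median -0.61 and 0.12), the tricarboxylic acid cycle (-0.62 and -0.46) and hexose transporters (-1.01 and -0.75) no longer stood apart below it, although the mean of the glycolysis list at 3.5 h (-0.78) did. Of 27 chaperone and chaperonin genes, 20 were at least 2-fold higher at 3.5 h (median 1.79) and 17 at 6 h (median 1.18), with hsp10 at 2.95 and 2.66, hsp90 at 2.47 and 1.88 and ssa1 at 1.68 and 0.83. Ribosomal proteins reached a median of 2.62 at 3.5 h and 2.22 at 6 h, while ribosome biogenesis factors were at 1.49 and 0.68, with 103 and 45 of 135 genes 2-fold higher. The cyclin gene cig2 stood at 2.84 and 3.31, the replication initiator gene cdc18 at 2.67 and 1.85, the ribonucleotide reductase gene cdc22 at 1.60 and 1.20, and mik1 at 1.62 and 1.31. Below G0, autophagy (-1.54 and -1.31), peptidases (-1.42 and -1.25), stress response (-0.97 and -1.06), nitrogen starvation (-1.01 and -0.64) and sexual differentiation (-1.16 and -0.99) stood apart at both times, with zym1 at -7.30 and -7.39 and the pheromone gene mfm3 at -6.89 and -6.61. The list of nutrient signalling and quiescence kinases stood apart as well (-0.60 and -0.47), though at 6 h not among genes with all values (-0.33), with tor1 at -0.32 and -0.12 and rum1 at -1.18 and -1.31. Out of 4779 genes on each array, 902 were 2-fold higher and 800 lower at 3.5 h, and 744 higher and 712 lower at 6 h. With each block of the 3.5 h array centred on its median the split was 707 higher and 994 lower, and the gene median of that array was 0.14.

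Vegetative cells differed from G0 cells in the same 8 lists above and 6 lists below as the 6 h cells. Of these, RNA polymerase I and III (median 0.60) no longer stood apart with the first of repeated spots (0.56) or with the list mean (0.50). Ribosomal proteins had a median of 1.92 with 118 of 123 at least 2-fold higher, translation factors 1.22 with 22 of 39, chaperones 1.13 with 14 of 26 and amino acid synthesis 0.97 with 37 of 77. Ribosome biogenesis factors stood at 0.70 with 41 of 134 higher. The lowest genes were the pheromone genes mfm3 (-8.36) and mfm1 (-7.83), SPAC869.04 (-7.82), SPAC869.03c (-6.85), zym1 (-6.55) and the pyruvate decarboxylase gene pdc201 (-6.53), and the pheromone receptor gene mam2 stood at -5.75. Near-identical genes such as mfm1 and mfm3 may share signal on cDNA spots, so their separate values are uncertain. The highest gene was adg1 (4.80), which stood at -0.82 at 6 h. Among genes also at least 1.5-fold above G0 at 6 h the highest were met17 (4.78), SPBPB10D8.02c (4.65), the biotin transporter gene vht1 (4.50) and SPAC8E11.10 (4.36). Sexual differentiation genes had a median of -1.46 with 18 of 32 lower, including ste11 (-2.32). Out of 4765 genes, 753 were 2-fold higher and 696 lower. With arrays centred on their medians, lower genes outnumbered higher ones in vegetative cells (656 higher and 777 lower), at 1 h (1070 and 1134), at 3.5 h (762 and 943) and at 6 h (715 and 741), and with each block centred the vegetative split was 611 and 806.

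**Figure D1:**
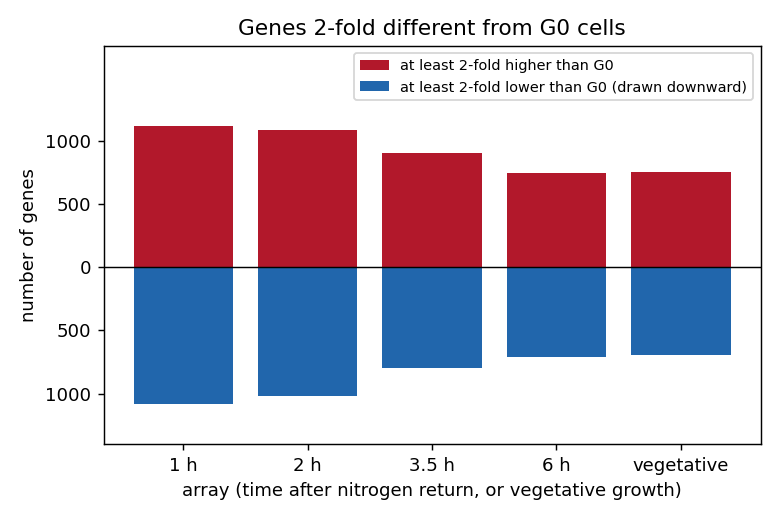
Number of genes at least 2-fold higher (bars upward) or lower (bars downward) than in G0 cells on each of the 5 arrays, 1 array per bar and so without error bars. Higher genes number 1118 at 1 h and 753 in vegetative cells.

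**Figure D2:**
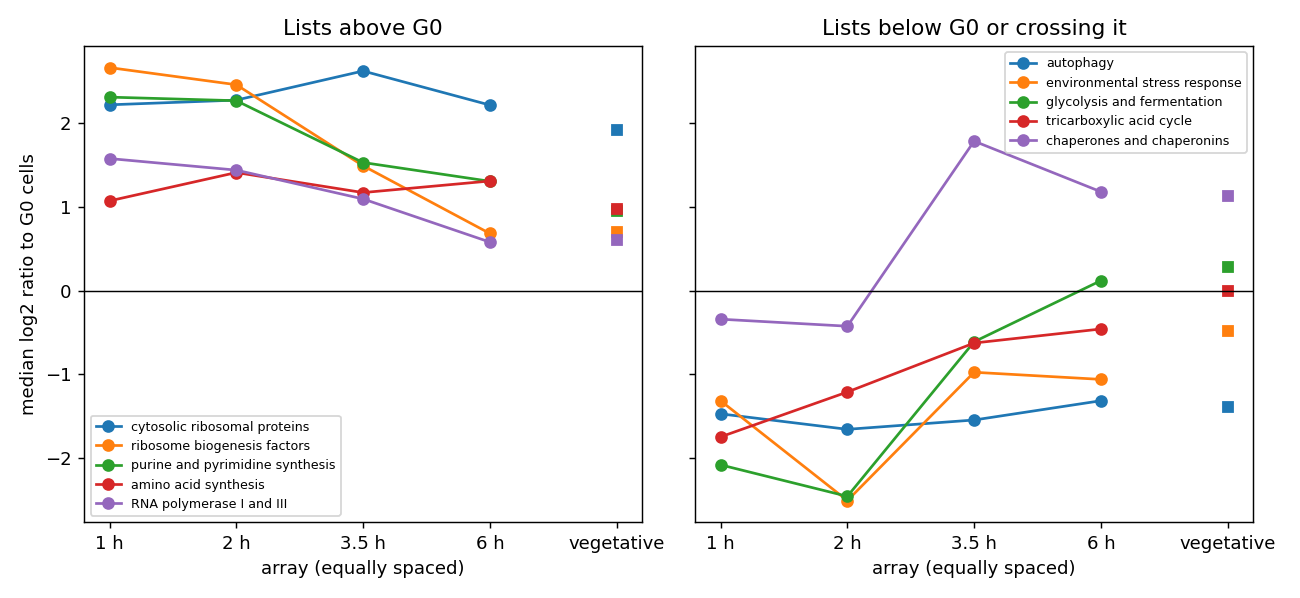
Median log2 ratio to G0 cells (vertical axis) of 10 gene lists on the 5 arrays (horizontal axis, not to time scale); circles joined by lines are the time course and squares vegetative cells. Ribosome biogenesis factors go from 2.66 at 1 h to 0.68 at 6 h, and chaperones from -0.42 at 2 h to 1.79 at 3.5 h.

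Between 1 h and 2 h, stress genes were lower at the later time. The stress response list differed by a median of -1.12, with 18 of 33 genes at least 2-fold lower and 1 higher. Among the lower ones were lsd90 (-5.62), rds1 (-4.88) and the glycerol phosphate dehydrogenase gene gpd1 (-4.72). The medians of sexual differentiation (-0.38, 8 of 32 genes 2-fold lower and 1 higher), histones (-0.59, 1 of 10 lower) and meiosis (-0.20, 11 of 147 lower and 6 higher) also stood apart below 0, with most members under the 2-fold limit. The same held above 0 for the medians of amino acid synthesis (0.26, 5 of 77 genes 2-fold higher and 6 lower), sterol and fatty acid synthesis (0.40, 5 of 30 higher and 2 lower) and cell wall synthesis (0.32, 2 of 33 higher and 1 lower). The meiosis call was lost with the list mean (-0.20). The histone call was lost with the list mean (-0.53), and the cell wall call with scaled arrays (0.26) and with the list mean (0.24). With centred arrays the histones (-0.54) lay at the 0.53rd percentile against the 0.36th. Centring cannot change a rank, so that move came from redrawn random lists. Of 4755 genes, 222 were 2-fold higher and 356 lower at 2 h. With arrays scaled to 1 median absolute deviation these were 110 and 278.

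Between 2 h and 3.5 h, more genes differed than at any other successive step, 554 higher and 497 lower at 3.5 h of 4767. Glycolysis, hexose transporter and chaperone genes were higher at 3.5 h. Among the genes that were higher, the largest differences were those of mug14 by 7.64, the invertase gene inv1 by 5.60, ght3 by 5.47 and fbp1 by 5.45, followed by the heat shock protein genes ssa1 by 4.83 and sti1 by 4.79. The chaperone list differed by a median of 1.87 (15 of 27 genes 2-fold higher and 0 lower), glycolysis by 1.46 (11 of 20 higher and 1 lower) and hexose transporters by 1.64 (4 of 8 higher and 1 lower). Targets and regulators of the G1/S transcription factor MBF differed by 0.70, with 14 of 30 genes 2-fold higher and 0 lower. That list, however, did not stand apart from G0 on any array. Stress response genes had a median difference of 0.74 (16 of 33 genes 2-fold higher and 4 lower), which did not stand apart with scaled arrays (0.39). The medians of actin and tubulin (0.56, 8 of 25 genes higher), the proteasome (0.46, 2 of 37), ribosomal proteins (0.38, 7 of 121) and meiosis (0.37, 14 of 144 higher and 9 lower) also stood apart above 0. Those of purine and pyrimidine synthesis (-0.72, 5 of 19 lower and 1 higher), RNA polymerase I and III (-0.46, 4 of 32 lower) and cell wall synthesis (-0.41, 6 of 33 lower and 1 higher) stood apart below 0. With scaled arrays the actin and tubulin (0.49), proteasome (0.38), purine (-0.37), polymerase (-0.18) and cell wall (-0.33) calls were lost. List means lost the proteasome (0.30) and the actin and tubulin (0.58) calls. With centred arrays the proteasome (0.33) lay at the 99.44th percentile against the 99.61st. Centring cannot change a rank, so that move too came from redrawn random lists. Lower at 3.5 h were psu2 (-8.83), the phosphate transporter gene pho842 (-5.54) and ribosome biogenesis factors (median -0.80, 46 of 135 genes). This step also crosses the 2 sets of columns, so the times cannot be told apart from the sets. Centred on array medians the split was 439 higher and 625 lower.

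Between 3.5 h and 6 h, histone genes and the thiamine synthesis genes nmt1 and thi2 were higher at 6 h. Of 10 histone genes, 8 were 2-fold higher (median difference 1.43): hta1 went from -0.43 to 1.16, htb1 from -0.23 to 1.51 and hhf1 from -0.96 to 0.71. The list holds gene copies such as hhf1, hhf2 and hhf3, which may share signal on cDNA spots. Its members may thus not be separate measurements, as random lists assume. The nmt1 ratio went from -0.30 to 3.80 and thi2 differed by 2.87, and SPAC11D3.14c (-5.34) and dgc1 (-4.51) were lower. Other list medians stood apart with most members under the 2-fold limit. Above 0 were those of glycolysis (0.66, 4 of 20 genes 2-fold higher), actin and tubulin (0.52, 3 of 25), the tricarboxylic acid cycle (0.49, 2 of 18), iron, copper and phosphate uptake (0.45, 6 of 21), sterol and fatty acid synthesis (0.44, 6 of 30), the proteasome (0.43, 1 of 37), autophagy (0.28, 0 of 33) and the stress response (0.24, 6 of 34 higher and 2 lower). Below 0 were those of ribosome biogenesis (-0.77, 35 of 135 genes 2-fold lower), RNA polymerase I and III (-0.53, 2 of 32), ribosomal proteins (-0.41, 0 of 122) and meiosis (-0.29, 3 of 143 lower and 4 higher). With arrays scaled to 1 median absolute deviation, ribosomal proteins (-0.011), autophagy (-0.022), the stress response (0.19) and the tricarboxylic acid cycle (0.34) no longer stood apart. With list means neither the tricarboxylic acid cycle (0.31) nor autophagy (0.22) did. Of 4768 genes, 197 were 2-fold higher and 136 lower, or 254 and 94 when centred on array medians.

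Between 6 h and vegetative growth, 8 of 38 genes of the cytokinesis and septation list were at least 2-fold higher in vegetative cells and 0 were lower. The median of the list (0.16) did not stand apart, whereas its mean (0.55) did. The difference was 5.62 for adg1, 3.23 for the glucanase gene agn1 and 2.84 for adg3, and eng1, a septum glucanase gene, stood at 0.18 at 6 h and 2.82 in vegetative cells. The mitotic activator gene slp1 stood at 0.87 and 2.70, and plo1 at -0.12 and 0.45. The medians of the stress response (0.41, 3 of 34 genes 2-fold higher and 2 lower) and the respiratory chain (0.37, 1 of 46 higher) stood apart above 0. Lower in vegetative cells were SPBC23G7.13c (-3.81), the siderophore transporter gene str3 (-2.19), met1 (-2.12) and the glutamate dehydrogenase gene gdh2 (-2.11), and the medians of amino acid synthesis (-0.40, 10 of 77 genes 2-fold lower), purine and pyrimidine synthesis (-0.53, 4 of 19), aminoacyl-tRNA synthetases (-0.39, 1 of 22 lower and 1 higher), ribosomal proteins (-0.32, 0 of 123), sexual differentiation (-0.28, 7 of 32) and nitrogen starvation (-0.25, 4 of 33) stood apart below 0. Of 4756 genes, 144 were 2-fold higher and 121 lower, or 128 and 147 when centred on array medians. With arrays scaled to 1 median absolute deviation these were 227 and 212.

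**Figure D3:**
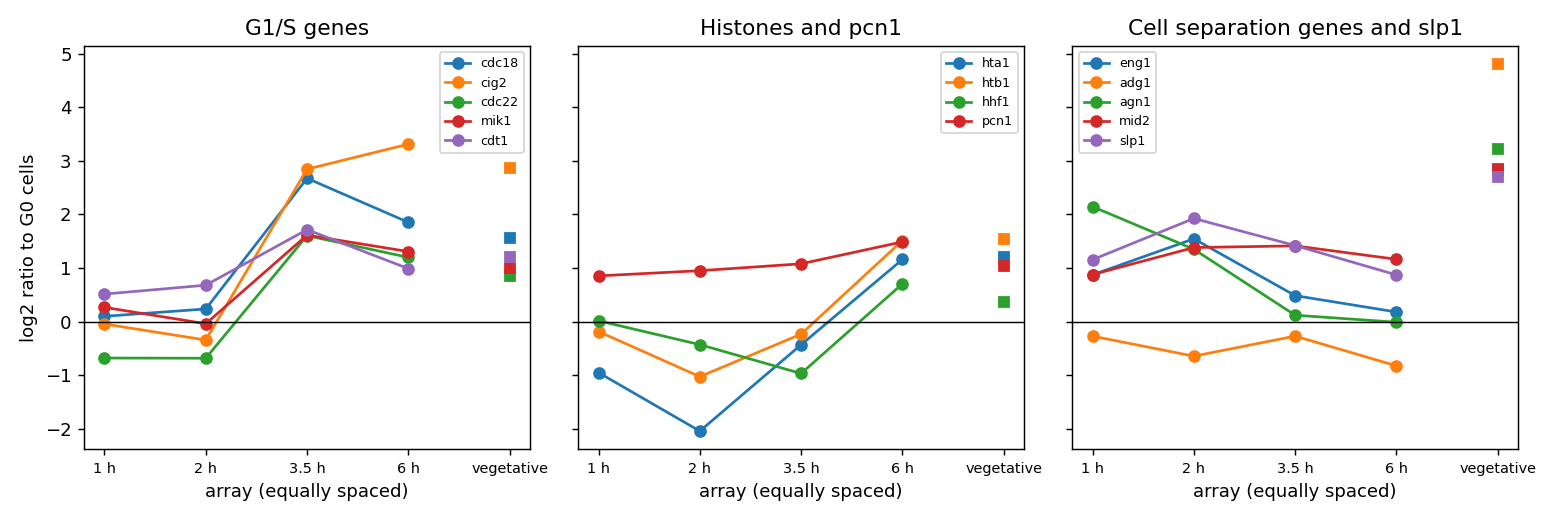
Log2 ratio to G0 cells (vertical axis) of 14 cell cycle genes on the 5 arrays (horizontal axis, not to time scale), 1 value per gene and array; circles joined by lines are the time course and squares vegetative cells. The cdc18 ratio is 0.24 at 2 h and 2.67 at 3.5 h, that of htb1 -0.23 at 3.5 h and 1.51 at 6 h, and that of adg1 -0.82 at 6 h and 4.80 in vegetative cells.

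Between 1 h and vegetative growth, carbon metabolism and the cytoskeleton were higher in vegetative cells and ribosome production lower. Glycolysis genes differed by a median of 2.33 (15 of 20 genes 2-fold higher and 3 lower), the tricarboxylic acid cycle by 1.58 (11 of 18 higher and 1 lower), actin and tubulin by 1.36 (18 of 25 higher), the proteasome by 0.98 (18 of 37 higher and 2 lower) and the respiratory chain by 0.93 (20 of 46 higher). Chaperones (1.46, 15 of 26 higher and 3 lower), sterol and fatty acid synthesis (0.96, 15 of 30 higher and 2 lower) and MBF targets and regulators (0.69, 13 of 29 higher and 2 lower) also stood apart above 0. The last did not with medians of repeated spots, where the same median lay at the 99.41st percentile of redrawn random lists, against the 99.645th. Ribosome biogenesis factors differed by -1.87, with 114 of 133 genes 2-fold lower, and purine and pyrimidine synthesis by -1.36 (16 of 19). RNA polymerase I and III (-0.87, 15 of 32 lower), nitrogen starvation (-0.85, 13 of 33 lower and 6 higher) and sexual differentiation (-0.67, 13 of 32 lower and 1 higher) stood apart below 0 too. With arrays scaled to 1 median absolute deviation purine and pyrimidine synthesis (-0.72) and the polymerases (-0.43) no longer did. Ribosomal proteins differed by -0.37, or 0.44 with the same scaling, and their mean (-0.30) did not stand apart. Of 4738 genes, 935 were 2-fold higher and 965 lower, across the 2 sets of columns.

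Lists whose medians stood apart on no array against G0 included DNA replication proteins (medians 0.09 to 0.36), mitosis and chromosome segregation (-0.18 to 0.15), cytokinesis and septation (-0.41 to -0.06) and splicing and mRNA export (0.03 to 0.36). Meiosis and spore formation (-0.18 to 0.21), cell wall synthesis (0.13 to 0.60), sterol and fatty acid synthesis (-0.39 to 0.51) and uptake of iron, copper and phosphate (0.27 to 0.45) did not either. The means of 3 of these lists did on some arrays: iron, copper and phosphate uptake at 6 h (0.88) and in vegetative cells (0.89), sterol and fatty acid synthesis at 6 h (0.52) and in vegetative cells (0.53), and meiosis at 2 h (-0.41), 6 h (-0.29) and in vegetative cells (-0.24, against a median of 0.11). Within these lists single genes were far from G0, such as the replication clamp gene pcn1 at 1.49 at 6 h, the glucanosyltransferase gene gas1 at 5.30 at 2 h and mug14 at -7.21 at 2 h.

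Over the 4 time course arrays, limma with Benjamini-Hochberg adjustment called 193 genes with a rising and 240 with a falling trend in log2 time among 4730. The steepest rises were those of mug14 (slope 3.15 ± 0.75 SE per doubling of time, limma adjusted p = 0.0461), inv1 (2.70 ± 0.52 SE, limma adjusted p = 0.0372) and idn1 (2.61 ± 0.31 SE, limma adjusted p = 0.0299). The steepest falls were those of psu2 (-4.56 ± 0.77 SE, limma adjusted p = 0.0323) and SPBPB7E8.01 (-2.43 ± 0.45 SE, limma adjusted p = 0.0343). In time order mug14 stood at -6.88, -7.21, 0.43 and -0.31, and psu2 at 7.16, 6.72, -2.12 and -3.09. All genes named here moved most between 2 h and 3.5 h, where the 2 sets of columns meet. Their slopes thus cannot be told apart from a difference between the sets. The p-values rest on scatter around a line over 4 single arrays and do not measure replicate error. With a robust prior limma lost the calls of mug14 (adjusted p = 0.203), inv1 (adjusted p = 0.144), psu2 (adjusted p = 0.124) and SPBPB7E8.01 (adjusted p = 0.109), and after centring that of mug14 (adjusted p = 0.0560). The counts changed with the array left out and with the time scale. Without the 3.5 h array limma called 0 rising and 0 falling genes (502 and 530 at an unadjusted p under 0.05). It called 3 and 4 without the 6 h array, 396 and 371 without the 1 h array and 503 and 560 without the 2 h array. In hours limma called 0 and 0 (651 and 710 unadjusted), and with the set of columns as a second term 0 and 0 (103 and 142 unadjusted). Fits without an array or with the set term left 1 residual degree of freedom. Lost calls there cannot be told apart from lost power. Without the 2 h array the estimated prior degrees of freedom were infinite, so those calls rested on 1 scatter shared by all genes.

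Many of the same genes differed from G0 early and late. Of the 4708 genes with all values, 486 were 2-fold higher both at 1 h and at 6 h and 428 were lower at both, where independent lists would share 174 and 160. At 1 h and in vegetative cells 452 were higher and 393 lower (independent lists 176 and 157), and at 6 h and in vegetative cells 565 were higher and 535 lower (independent lists 116 and 103). Simulated unchanged arrays with 1 shared G0 channel gave between 28.6 and 29.4 shared genes in each case. Their SD per channel (0.38) came from the difference between the 6 h and vegetative arrays, which cancels a shared G0 channel. The scatter of G0 RNA was thus not measured, and these counts do not give the share due to the common control. All arrays have G0 RNA as their denominator and it cannot be split, so part of the excess may come from the shared control.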

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

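All tests in this part were chosen after the results were seen, and the differences between arrays named here were not tested, since each condition had 1 array.

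Among the marker genes, 3 were at least 2-fold below G0 on 1 array and at least 2-fold above it on another. The glutamate dehydrogenase gene gdh1 was at -2.64 at 1 h and 1.40 at 6 h. The histone genes hta1 and htb1 were at -2.04 and -1.02 at 2 h and at 1.20 and 1.54 in vegetative cells. Of 101 spots that carry no gene name here and have all values, 12 were at least 2-fold above G0 on all 5 arrays and 6 were below it on all 5.

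More genes differed 2-fold between 2 h and 3.5 h (1051) than between other successive arrays (578 from 1 h to 2 h, 333 from 3.5 h to 6 h, 265 from 6 h to vegetative growth). With every array centred and scaled to 1 median absolute deviation the step still had 903 such genes against 394, 451 and 460, and the most in 16 of 16 blocks, which argues against 1 scale factor and 1 offset between the 2 sets of columns as the whole cause. Around straight-line fits 746 genes lay 2-fold off, against 523, 249 and 235. Of 205 genes that differed 4-fold at this step, 58.0% moved under 2-fold at every other step. The same share was 26.1% of 111 genes from 1 h to 2 h, 11.1% of 27 from 3.5 h to 6 h and 35.5% of 31 from 6 h to vegetative growth. Genes of those steps had to be flat from 2 h to 3.5 h, the step with the most moving genes. Their lower shares are thus partly built in. A different G0 RNA, or another gene-specific difference between the sets, and a rapid change in the cells would both give a high share at this step. They cannot be told apart because the sets split the time course at the same place.

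Glucose-repressed genes, a list of 9 written after the data were seen, had a median of -5.16 at 1 h and -4.62 at 2 h but -1.03 at 3.5 h and -0.90 in vegetative cells. No explanation was tested, since the list was chosen for these values. Nitrogen came back with fresh medium, so a response to nitrogen cannot be told apart from a response to the medium.

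Chaperone and chaperonin genes stood above G0 from 3.5 h on, with list medians of 1.79 at 3.5 h, 1.18 at 6 h and 1.13 in vegetative cells. A different G0 RNA between the sets stays open, since 19 of 26 genes were higher on all 3 arrays of the later set than on both of the first, against 1306 of all 4708 genes (27.7%, where arrays in no order would give 10%). A biological change between 2 h and 3.5 h and heat or handling of the cultures stay open too and were not tested.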

How the results depend on the processing

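The natural-log reading, block centring, the set of columns as a trend term and the proteasome list without pus1 were chosen after seeing the data. Of 304 comparisons of a count with its value under an alternative, 249 lay within 1.5 times. Of 1810 comparisons of a list median 1746 gave the same call, 33 kept the sign but no longer stood apart, 29 newly did and 2 changed sign. Of these 2, autophagy from 3.5 h to 6 h also no longer stood apart. Much of the agreement in counts and list medians was fixed in advance. Other ways to combine spots reach only 4 genes. Centring cannot change a list's rank, and scaling cannot change its rank against G0. List calls that changed under those settings came from redrawn random lists. Of 9875 comparisons of a named gene's log2 ratio, 1564 moved by more than the SD between repeated spots, 994 of 1975 under scaling to 1 median absolute deviation and 567 of 1975 with each block centred. None that was 2-fold from G0 changed sign, but this was largely fixed in advance. Centring moved values by about 0.35 at most, scaling keeps the sign, and other ways to combine spots touch only 4 genes. Of 220 comparisons of a named gene's slope, 85 lost the call with the sign kept, and 6 more changed sign and lost it too. With no intensities, the effect of signal over background could not be examined, and the cause of the changes below was not tested except where a stricter or looser limit brings them about.

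With a 3-fold limit in place of 2-fold, genes higher and lower than in G0 cells numbered 728 and 623 at 1 h, 714 and 638 at 2 h, 470 and 436 at 3.5 h, 357 and 344 at 6 h and 322 and 342 in vegetative cells. Genes higher and lower in the later array then numbered 32 and 153 from 1 h to 2 h, 225 and 162 from 2 h to 3.5 h, 48 and 17 from 3.5 h to 6 h, 47 and 21 from 6 h to vegetative growth and 466 and 516 from 1 h to vegetative growth. Shared genes higher and lower numbered 252 and 192 at 1 h and 6 h, 210 and 180 at 1 h and in vegetative cells, and 243 and 257 at 6 h and in vegetative cells.

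Scaled to 1 median absolute deviation, genes higher at 2 h than at 1 h numbered 110, those lower at 6 h than at 3.5 h 208, and those from 6 h to vegetative growth 227 higher and 212 lower. Lists standing apart lower from 2 h to 3.5 h numbered 2 in place of 4. Under that scaling the median difference of ribosomal proteins from 1 h to vegetative growth turned from -0.37 to 0.44, and that of autophagy from 3.5 h to 6 h from 0.28 to -0.022.

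Read as natural logarithms, the values gave 1143 genes 2-fold higher in vegetative cells than in G0 cells. Genes higher and lower in the later array were then 538 and 632 from 1 h to 2 h, 940 and 845 from 2 h to 3.5 h, 434 and 449 from 3.5 h to 6 h and 349 and 317 from 6 h to vegetative growth.

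The limma trend counts were the least stable. Rising and falling genes numbered 347 and 432 with a trended prior, 0 and 0 in hours, and 0 and 0 with the set of columns as a second term; 142 fell after centring. Leaving out 1 array at a time, which left 1 residual degree of freedom, rising genes ranged from 0 to 503 and falling genes from 0 to 560. With the set of columns as a second term 6 of the 20 named slopes changed sign: mug14 to -0.56, ght3 to -0.079, gld1 to -0.13, sti1 to -0.27, pho842 to 0.27 and SPBC800.11 to 0.20.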

Other observations

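The gene lists and tests in this part were chosen after the data were seen.

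Genes of sulfate assimilation and methionine synthesis lay above G0 on all arrays, with medians over 15 genes of 3.43 at 1 h, 2.76 at 2 h, 2.50 at 3.5 h, 2.31 at 6 h and 1.24 in vegetative cells. At 1 h 13 of the 15 were at least 2-fold higher, with met17 at 5.69, met1 at 5.47, sam1 at 5.07, the sulfate transporter gene sul2 at 4.57 and cys2 at 4.45, and cys12 was lower at -1.37. A list of genes of thiamine and vitamin B6 synthesis and uptake, which also held the biotin transporter gene vht1 (4.73 at 6 h), was highest at 6 h, with a median of 3.75 over 8 genes and 7 of 8 at least 2-fold higher. The vitamin B6 transporter gene bsu1 was at 1.98 at 1 h and 4.96 at 6 h, the thiamine-repressible phosphatase gene pho4 at 0.86 and 4.01, and nmt1 at -0.69 and 3.80.

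Neighbouring protein-coding genes had slightly similar log2 ratios. The hypothesis tested was that they were spotted close together. Over 3064 neighbouring pairs in different blocks and more than 24 positions apart, the correlation across genes (genes are not independent replicates) was 0.0485 at 1 h, 0.0574 at 2 h, 0.0673 at 3.5 h, 0.0938 at 6 h and 0.0646 in vegetative cells. Over all 4290 pairs it was 0.0607, 0.0710, 0.0894, 0.105 and 0.0795. In one-sided permutation tests with 1000 shuffled gene orders, 1 test per array, the adjusted p of the far pairs was 0.00400 at 1 h, 0.00250 in vegetative cells and 0.00167 on the others, where the unadjusted p (0.001) is the smallest the shuffles can give. This argues against close spotting as the whole cause on the 5 arrays. The printing order is not given in the sources used here, and signal shared between neighbouring duplicated genes was not tested. The 5 ratios also share a G0 denominator, so they are not 5 separate tests.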
